A study of Gallus gallus with 24 samples.

How the data were processed

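Messenger RNA was sequenced from intestinal mesoderm of chick embryos, per the labels, after manual removal of the endoderm. RCAS is an avian retroviral vector that spreads through the tissue that receives it. Per the labels' protocols, a construct carrying either a GFP reporter (mGFP) or Hoxd13 was electroporated in ovo into the splanchnic lateral plate mesoderm at stage HH 17, and eggs were kept at 38 °C. The control groups were the midgut and the hindgut labelled RCAS-mGFP, and the third group was the midgut labelled RCAS-Hoxd13. The libraries were made with a stranded TruSeq kit for messenger RNA.

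The deposited values are estimated counts per Ensembl gene, given as whole numbers. Salmon, DESeq2 and the genome build GRCg6a are named without versions or roles, per the submitters' processing notes. The annotation release and any filter applied by the authors are not given in the sources used here. The values were taken as unnormalized, because they were whole numbers and their totals differed between libraries, so rounding changed none of them.

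The labels describe 24 samples, 12 at embryonic day 12 and 12 at embryonic day 14, in 2 tables. The 2 tables had different headers but differed in 0 lines below the header, over 205632 values. They were therefore treated as 1 set of 12 libraries, 4 per group, and the age these values belong to is not known. The comparisons of the ages, and of any change of an effect with age, had been planned and were not made.

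Genes appear only by Ensembl ID, and the files do not pair the IDs with symbols. The reference gene table, for the assembly GRCg7b, has 25635 rows with 0 filled cells in its Ensembl column, and 0 of the 17136 IDs matched it. The 34 gene lists fixed before the data were examined, among them signalling pathways, extracellular matrix, smooth muscle and markers of other cell types, had 0 matched members and were not tested. The check of the misexpressed gene by its symbol was not made either. The rule for named genes took HOXD13, the genes with the largest changes in each comparison, the genes common to both comparisons with the largest smaller change, and list members, each with a symbol. Without symbols it could not be applied. The 4 IDs named were chosen after their values were seen: they are the first 2 of the 77 higher and the first 2 of the 17 lower common genes that met the rule for common genes except its symbol condition, ranked by the smaller of their 2 absolute log2 fold changes. That rule asked for an average log2 CPM, the count scaled to the library total, of at least 2 and no overlap between the groups' libraries.

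Counts were tested in R 4.3.3 with edgeR 4.0.16, using a quasi-likelihood F test with robust dispersion estimation, TMM scaling and filterByExpr with its count minimum of 10. The filter left 12931 genes. The 3 groups entered a single fit with no further covariates, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were derived from the F statistic. CPM values use the TMM-scaled library totals. A gene was counted as common when it was called in the same direction in hindgut and in Hoxd13 midgut, each against the control midgut. The slope is the least-squares slope of the Hoxd13 log2 fold change on the hindgut log2 fold change over the genes called between hindgut and control midgut. Because both comparisons use the same 4 control midgut libraries, 50 sets of unchanged groups were simulated, and the controls were also split 2 and 2 in all 6 ways. The simulated libraries were drawn independently of each other, without pairs and without a library that stands apart.

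Totals ran from 7607185 to 10880695 counts per library, and the median standard error of a log2 fold change was 0.222 in hindgut against midgut. The labels do not say whether replicates came from separate embryos, so the p-values measure the spread between these samples, which may be technical. Replicate pairs differed by 15.4 to 121 times the sampling variance of counts, so no library was counted as a repeat of another.

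Replicate numbers were checked for pairing through the correlation, across genes, of each library's deviations from its group mean. Control midgut and control hindgut libraries of the same number correlated at 0.489, 0.435, 0.528 and 0.531 for numbers 1 to 4, and each library matched its own number best. The numbers were therefore taken to pair these 2 groups, from the data and not from the labels. The fit fixed before the data were examined has no block and gives the values reported, with the count under the block beside the comparison of hindgut with midgut. Same-numbered control midgut and Hoxd13 midgut libraries correlated at 0.178, -0.232, 0.0435 and -0.119, and same-numbered hindgut and Hoxd13 midgut libraries at 0.0772, -0.240, 0.121 and -0.358, so those numbers were not taken as pairs.

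The test was checked on counts simulated for the 12931 genes. In hindgut against midgut it recovered 56% of 100 genes changed 2-fold and 88% of 100 changed 4-fold, with 6 false calls among 150. For Hoxd13 midgut against midgut it recovered 38% of 50 genes changed 2-fold and 94% of 50 changed 4-fold, with 3 false calls among 69. For Hoxd13 midgut against hindgut it recovered 50% of 50 changed 2-fold and 76% of 50 changed 4-fold, with 3 false calls among 66. Of 100 simulated common genes 63 were found, and a simulated slope of 0.5 was estimated as 0.531. These simulated counts held no pairs and no library that stands apart as Hoxd13 midgut 4 does, so the rates may not hold for the real counts.

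Alternatives chosen before the data were examined were DESeq2's size factors, no filter, DESeq2 1.42.0, limma 3.58.1 (voom with sample quality weights), a replicate block, fits of only the groups compared, an absolute log2 fold change of at least 1, leaving out each library, and the split controls. A mean count of at least 100, and a replicate block in a fit of only the control libraries, were chosen after seeing the data.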

Results

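Gene expression was measured by RNA sequencing in the mesoderm of chick midgut carrying a control virus, hindgut carrying the control virus, and midgut carrying a virus that expresses Hoxd13, a Hox transcription factor gene. Each group had 4 libraries. Mean totals were 9702717 ± 1065578 counts in control midgut, 10027472 ± 669377 in control hindgut and 9210475 ± 1194601 in Hoxd13 midgut (SD, n = 4 each). Genes are given by Ensembl ID because the files do not pair them with symbols, and the embryonic age of these values, day 12 or day 14 in the labels, is not known. Hoxd13 midgut 4 stood apart from the other libraries. It had counts in 13480 genes against 14702 ± 90.2 (SD) in the other 11 libraries, and its 100 most abundant genes took 34.0% of its counts against 21.7% to 24.1%. The first principal component of log2 CPM held 51.5% of the variance, with Hoxd13 midgut 4 at 141 and the next library, Hoxd13 midgut 3, at 50.1. Values without Hoxd13 midgut 4 are given in each comparison.

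**Figure D1:**
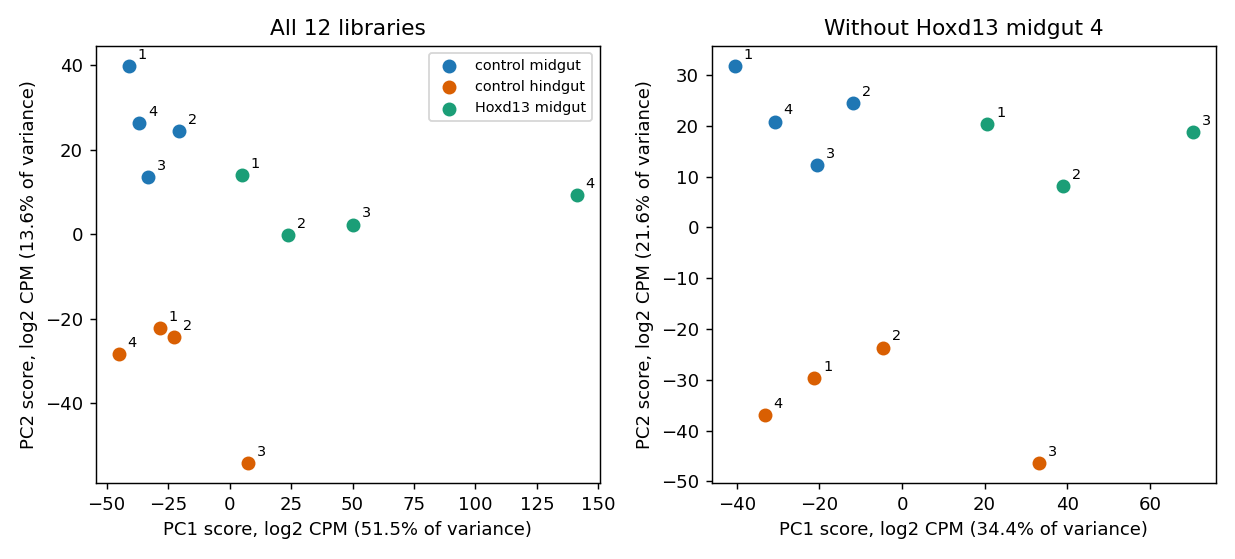
Principal component scores of the libraries from log2 CPM, with all 12 libraries (left) and without Hoxd13 midgut 4 (right). Each point is a library, coloured by group and numbered by replicate, and the axes give the share of variance. With all libraries Hoxd13 midgut 4 lies at 141 on the first component, and without it the first 2 components hold 34.4% and 21.6% of the variance.

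The comparison of hindgut with midgut asked which genes differ in the dissected mesoderm of the regions that form the large and the small intestine. Whether the mix of cells differed between the groups was not tested, because the genes carry no names. Of the 12931 genes tested, 305 were higher in control hindgut and 137 were lower. The median change was 2.65-fold among the higher genes and 2.76-fold among the lower genes, and 317 of the 442 differed by at least 2-fold. ENSGALG00000027960 rose from 0.623 ± 0.263 CPM in control midgut to 17.1 ± 3.92 CPM in hindgut (SD, n = 4 each), a log2 fold change of 4.77 ± 0.38 (SE, edgeR adjusted p = 1.41e-05). ENSGALG00000032039 rose from 0.423 ± 0.432 to 33.8 ± 18.5 CPM, a log2 fold change of 6.28 ± 0.75 (SE, edgeR adjusted p = 0.000475). ENSGALG00000037262 was at 454 ± 164 CPM in control midgut and at 0.364 ± 0.439 CPM in hindgut, a log2 fold change of -10.29 ± 1.21 (SE, edgeR adjusted p = 0.000473). ENSGALG00000016364 fell from 19.3 ± 1.93 to 2.11 ± 0.366 CPM, a log2 fold change of -3.19 ± 0.41 (SE, edgeR adjusted p = 0.000682). In 441 of the 442 genes the libraries of the groups did not overlap, as in 14.3% of all tested genes, where chance gives 2.86%. With the replicate numbers as a block in a fit of the control libraries, 976 genes were higher and 522 lower in hindgut, 1498 in all, with 438 of the 442 among them and median changes of 1.64-fold and 1.51-fold. The count was 892 without Hoxd13 midgut 4, with all 442 among them and 422 of the 892 at 2-fold or more, and 291, 287, 291 and 289 without control midgut 1, 2, 3 and 4.

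The comparison of Hoxd13 midgut with control midgut asked which genes change when Hoxd13 is expressed in a region outside the hindgut. Expression of 329 genes was higher in Hoxd13 midgut and of 503 lower. The higher genes changed by a median of 2.00-fold and the lower genes by 3.76-fold. ENSGALG00000032039 showed the largest rise among the called genes, to 3979 ± 2358 CPM (SD, n = 4), a log2 fold change of 13.16 ± 0.90 (SE, edgeR adjusted p = 8.66e-05), where the next largest was 7.31. Its level was 1917, 2874, 3805 and 7322 CPM in Hoxd13 midgut 1, 2, 3 and 4, against 0 to 0.847 CPM in the control midguts. Whether this ID is Hoxd13 itself could not be checked without symbols. Its rise may therefore be the transcript of the virus and not a response to it. It was kept among the common genes and in the slope. ENSGALG00000027960 rose to 7.01 ± 2.67 CPM (SD, n = 4), a log2 fold change of 3.48 ± 0.38 (SE, edgeR adjusted p = 0.00152). Without Hoxd13 midgut 4 the counts were 184 higher and 119 lower, with 258 genes in common with all libraries, and the lower genes then changed by a median of 2.01-fold. The larger number of lower genes did not hold in 10 of 20 alternatives, where more genes were higher. The share of higher genes was 39.5% with all libraries and 52.2% without a filter on low counts. It was 84.3%, 54.8%, 82.2% and 85.4% without control midgut 1, 2, 3 and 4, 75.3% and 79.3% without control hindgut 1 and 2, and 58.7%, 92.3% and 60.7% without Hoxd13 midgut 2, 3 and 4. The total of 832 depended on single libraries: it was 51, 115, 45 and 41 without control midgut 1, 2, 3 and 4, 97 and 87 without control hindgut 1 and 2, and 2726, 39 and 303 without Hoxd13 midgut 1, 3 and 4. At an unadjusted p under 0.05 there were 4003 genes.

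The named genes were chosen among those called in the same direction in both comparisons, so their direction in Hoxd13 midgut was set by the choice. ENSGALG00000037262 was at 24.3 ± 25.7 CPM in Hoxd13 midgut (SD, n = 4), a log2 fold change of -4.21 ± 0.85 against control midgut (SE, edgeR adjusted p = 0.0356). ENSGALG00000016364 was at 5.23 ± 3.74 CPM, a log2 fold change of -1.88 ± 0.38 (SE, edgeR adjusted p = 0.0338). These calls depended on single libraries. For ENSGALG00000037262 the edgeR adjusted p was 0.10, 0.053, 0.077 and 0.085 without control midgut 1, 2, 3 and 4, 0.054 and 0.055 without control hindgut 1 and 2, and 0.11 without Hoxd13 midgut 3, with log2 fold changes from -3.95 to -4.37. For ENSGALG00000016364 the edgeR adjusted p was 0.10, 0.056, 0.073 and 0.085 without control midgut 1, 2, 3 and 4, 0.052 and 0.055 without control hindgut 1 and 2, and 0.075 without Hoxd13 midgut 3, with log2 fold changes from -1.61 to -1.94, and it was 0.052 in a fit of only the compared groups. Those ranges cover only alternatives that lost the call. Without Hoxd13 midgut 1 both calls were kept, with larger log2 fold changes of -5.17 for ENSGALG00000037262 and -2.50 for ENSGALG00000016364. Over all alternatives the adjusted p ran from 0.000648 to 0.11 for ENSGALG00000037262 and from 0.000132 to 0.10 for ENSGALG00000016364.

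**Figure D2:**
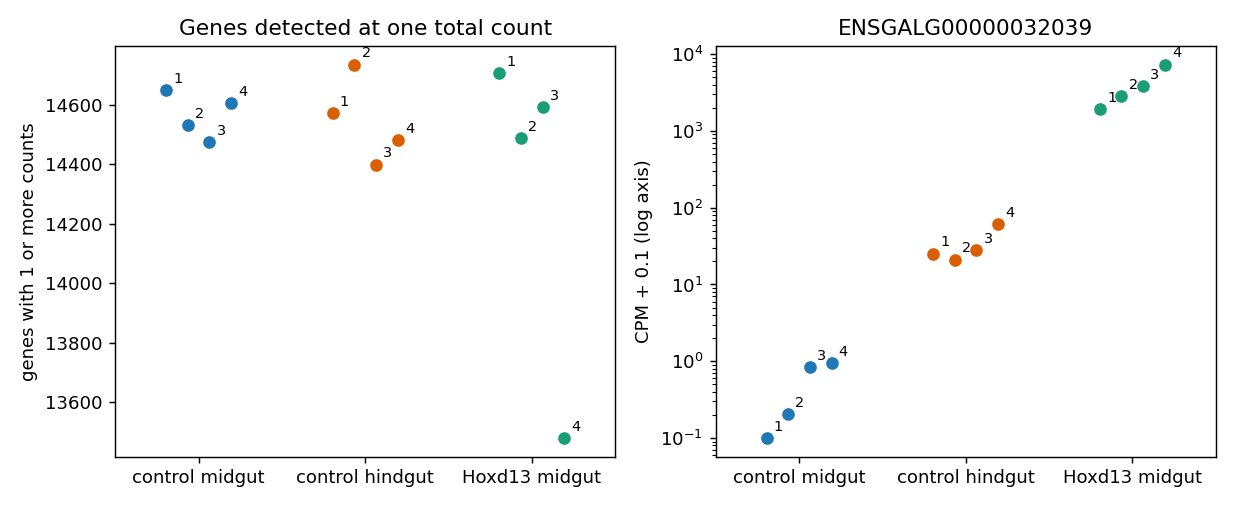
Left, genes with 1 or more counts per library after all libraries were thinned to 7607185 counts. Right, CPM of ENSGALG00000032039 per library, plus a small offset, on a log axis. Points are libraries, coloured by group and numbered by replicate. Hoxd13 midgut 4 has 13480 genes where the other 11 libraries have 14399 to 14735, and ENSGALG00000032039 reaches 1917 to 7322 CPM in the 4 Hoxd13 midguts.

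Against control hindgut, Hoxd13 midgut had 251 genes higher and 272 lower, with median changes of 2.14-fold and 2.46-fold. ENSGALG00000032039 was 118-fold higher in Hoxd13 midgut than in hindgut, a log2 fold change of 6.88 ± 0.68 (SE, edgeR adjusted p = 0.00025). ENSGALG00000027960 stayed below its hindgut level, with a log2 fold change of -1.29 ± 0.30 (SE, edgeR adjusted p = 0.0351). ENSGALG00000037262 stayed above its hindgut level by a log2 fold change of 6.08 ± 1.11 (SE, edgeR adjusted p = 0.0126). For ENSGALG00000016364 the log2 fold change of 1.32 ± 0.40 did not pass the test (SE, edgeR adjusted p = 0.0718). Without Hoxd13 midgut 4 the counts were 319 higher and 428 lower, with 478 genes in common with all libraries. The total of 523 was 325 and 322 without control midgut 3 and 4, 240, 242, 984 and 189 without control hindgut 1, 2, 3 and 4, and 2765 and 301 without Hoxd13 midgut 1 and 3. Without Hoxd13 midgut 2 the balance turned, with 267 genes higher and 192 lower.

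The comparison of both sets of changes asked which genes differ from control midgut in the same way in the hindgut and under Hoxd13. In 90 genes expression was higher in both, and in 18 it was lower in both. The 108 genes compare with 13.1 for independent lists of these sizes, 7.76 higher and 5.33 lower, and 4 genes were called in opposite directions. They made up 29.5% of the genes higher in hindgut and 13.1% of those lower in hindgut. The difference between these shares was not tested. Without Hoxd13 midgut 4 there were 115 common genes, 94 higher and 21 lower, against 11.2 for independent lists, and 77 of them were among the 108. They then made up 15.1% of the genes higher in hindgut and 7.75% of those lower, and 6 genes were called in opposite directions. In 50 simulations of unchanged groups against the shared controls, edgeR called 0 common genes, a count that says little about shared controls because unchanged groups give few calls. In these simulations 110 to 156 genes moved the same way in both comparisons at an unadjusted p under 0.05, against 542 observed. The simulated libraries were independent, and a regrouping of the real libraries gave 596 such genes, so the unadjusted count does not set the real groups apart. With the control midguts split between the comparisons, 1 to 5 genes were common, against 0.00887 to 0.163 for independent lists. Without Hoxd13 midgut 4 the same splits gave 15 to 25 common genes, against 0.545 to 1.47. The count of 108 was 27, 35, 24 and 23 without control midgut 1, 2, 3 and 4, 43 and 40 without control hindgut 1 and 2, and 179 and 21 without Hoxd13 midgut 1 and 3.

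Among the 305 genes higher in hindgut, 259 (84.9%) also had a positive log2 fold change in Hoxd13 midgut, with a median of 0.49 against 1.40 in hindgut. Among the 137 genes lower in hindgut, 109 (79.6%) also had a negative value, with a median of -0.43 against -1.46. With separate controls the share of same-sign genes was 79.4% to 85.1%. Of the genes higher in hindgut, 140 were still called lower in Hoxd13 midgut than in hindgut. Of the genes lower in hindgut, 73 were still called higher. The genes not called were not shown to reach the hindgut level. All were chosen with the same hindgut libraries, which favours a remaining difference and a larger hindgut median. Without Hoxd13 midgut 4, 621 genes were higher in hindgut, of which 510 (82.1%) had the same sign in Hoxd13 midgut. Their median was 0.31 against 0.93 over the 621 genes, and 281 were still called lower than in hindgut. Of the 271 genes then lower in hindgut, 210 (77.5%) had the same sign. The median over the 271 was -0.27 against -0.98, and 130 were still called higher than in hindgut. The slope of the Hoxd13 change on the hindgut change over the 442 genes was 0.314, and it was 0.287 to 0.317 with separate controls. The slope was also computed from each Hoxd13 midgut library. There its log2 CPM, with an offset of 2, minus the control midgut mean replaced the fitted Hoxd13 log2 fold change. On that scale, which is not the scale of 0.314, the slope was 0.163, 0.201, 0.267 and 0.320 in Hoxd13 midgut 1, 2, 3 and 4. Its mean was 0.238 ± 0.0696 (SD, n = 4). The libraries had the same order in CPM of ENSGALG00000032039, from 1917 to 7322. They also had it on the first principal component, at 4.94, 23.9, 50.1 and 141. The share of counts in the 100 most abundant genes rose in this order, at 22.8%, 23.6%, 23.8% and 34.0%. The ratio of genes at 1 count to genes at 7 counts fell in it, at 3.48, 3.08, 3.06 and 1.52. The level of ENSGALG00000032039, which is itself among the 442 genes, can therefore not be told apart from these library measures. This order was seen after the fact and was not tested. Over all tested genes the covariance of the log2 fold changes was 0.180, against 0.0625 to 0.0817 in the simulations, a difference of 0.109 from their mean. The correlation across genes, which are not independent replicates, was 0.394, against a simulated mean of 0.506. The share of all genes with the same sign was 60.0% against 66.7%. Both lay below the lowest simulated values, 0.473 and 65.5%, so with shared controls these 2 measures do not exceed what unchanged groups give. With separate controls the correlation was 0.146 to 0.308, where the simulations reached at most 0.0832.

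**Figure D3:**
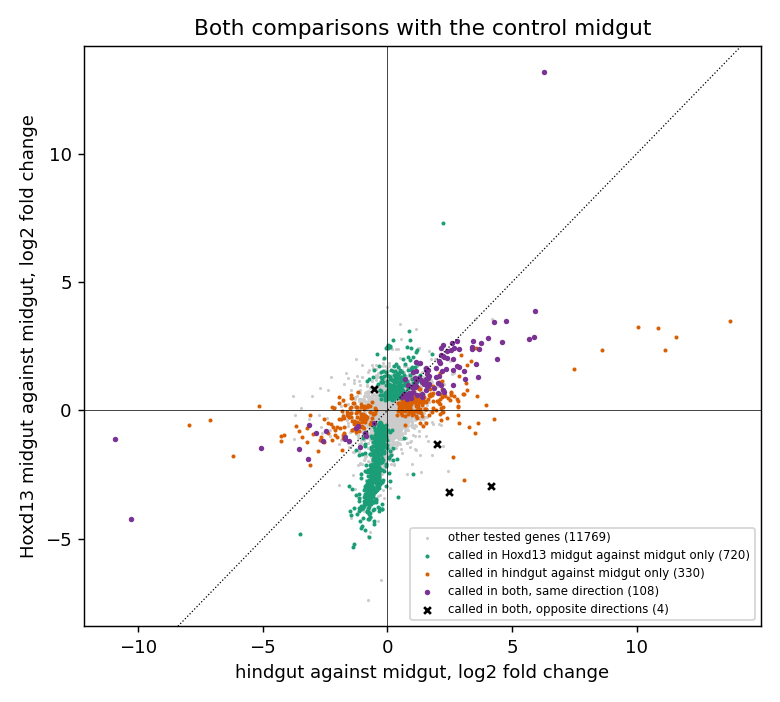
Log2 fold change in Hoxd13 midgut (vertical) against that in hindgut (horizontal), each relative to control midgut, for the 12931 tested genes. Points are genes coloured by where they were called, and the dotted line marks equal changes. Of the called genes, 108 moved the same way in both comparisons, 4 moved opposite ways, 330 were called only in hindgut and 720 only in Hoxd13 midgut.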

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

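The tests of sequencing depth and of low counts in Hoxd13 midgut 4 were chosen after its low number of genes was seen, and the slope over 4 genes was judged too thin to decide after its value was seen. Of 31 sets of 4 values tested for a library far from the rest, 3 held one, where chance gives about 1 in 20. Control midgut 1 had counts in 14818 genes, above the 14659 to 14670 of the other control midguts. After thinning to one total it had 14650 against 14475 to 14605, and it was not flagged. Hoxd13 midgut 4 had counts in 13480 genes, and its 100 most abundant genes took 34.0% of its counts. Per gene, Hoxd13 midgut 4 lay far from its group in 1185 of the 12931 genes (9.16%), and the other libraries in 0.271% to 2.00%.

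Lower depth does not account for Hoxd13 midgut 4: thinned to the same total, the other 11 libraries kept 14399 or more genes. Few starting RNA molecules could account for its low counts, since its ratio of genes at 1 count to genes at 7 counts was 1.52, against 3.06 to 4.42 in the other libraries. They do not account for its abundant genes, where the excess variance at mean counts of 1000 or more was 32.3 times that expected from sampling molecules. The expected value scaled the excess at mean counts of 10 to 30 with the inverse of the mean count. The size of 32.3 depends on that baseline. The excess itself was 0.844 at mean counts of 100 to 300 and 0.704 at 1000 or more. A stronger response to Hoxd13 may contribute, since its deviation from a held-out Hoxd13 midgut rose with the Hoxd13 effect of the remaining libraries, with slopes of 0.697, 0.176 and 0.102 over abundant genes with replicate 1, 2 and 3 held out. The last slope rests on 4 genes, and over genes of any abundance it was 0.0761 (40 genes, 60% with the same sign). With replicate 1 and 2 held out it was 0.855 (605 genes) and 0.407 (170 genes), so whether the response was stronger is left open. Poorer RNA was not tested, and a different mix of cells was not tested because the genes carry no names.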

How the results depend on the processing

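The fits with a mean count of at least 100, and with a block on only the control libraries, were chosen after seeing the data. The slope and the fold changes of the named genes kept their sign. More genes were higher than lower, against the reported balance, in 10 of 20 alternatives of Hoxd13 midgut against midgut and in 1 of 20 of Hoxd13 midgut against hindgut. The slope stayed at 0.293 to 0.331 in its 18 alternatives. None of them was set to leave out ENSGALG00000032039, which may be the transcript of the virus. ENSGALG00000032039 and ENSGALG00000027960 kept both calls in every alternative that tested them. ENSGALG00000037262 and ENSGALG00000016364 kept their hindgut calls and lost their Hoxd13 calls in 7 and 8 alternatives.

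Hindgut against midgut (442 genes) gave 701 with DESeq2, 1086 with voom, 259 at a mean count of at least 100, 909 in a fit of the compared groups, 1498 there with a block, and 287 to 892 without single libraries. Hoxd13 midgut against midgut (832) gave 299 without a filter, 2134 with DESeq2, 2096 with voom, 325 in a fit of the compared groups and 39 to 2726 without single libraries. Hoxd13 midgut against hindgut (523) gave 2183 with DESeq2, 1938 with voom, 316 at a mean count of at least 100, 152 in a fit of the compared groups, 329 at an absolute log2 fold change of at least 1, and 189 to 2765 without single libraries. Common genes (108) gave 205 with DESeq2, 293 with voom and 21 to 179 without single libraries. With split controls the median was 3.5, and it was 21.5 with Hoxd13 midgut 4 also left out. Fewer genes were tested at the higher count minimum and fewer libraries entered the smaller fits. Hindgut against midgut nonetheless rose from 442 to 909 in the smaller fit. Leaving out only Hoxd13 midgut 4, which is in neither group, gave 892. The median standard error of a log2 fold change was then 0.159, against 0.222 with all libraries. That library enters this comparison only through the filter, the scaling and the shared estimate of the spread. Otherwise the cause was not tested. In the fit of all libraries the replicate block gave 352, 654, 311 and 77 genes in the same order and a slope of 0.326. Numbers were not taken as pairs for Hoxd13 midgut. There 1 of 4 libraries matched its own number best among control midguts and none among hindguts. Hoxd13 midgut 4 enters the mean of its group and the check was not repeated without it, so pairs are not excluded. Planned comparisons of ages, and tests of gene lists and of genes by symbol, were not run.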

Other observations

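The tests of Hoxd13 midgut 4 for the common genes, and of an axis through the replicate numbers, were chosen after the results were seen. A search of the counts for genes switched between regions found 8 genes with at most 3 counts over the control midguts and at least 10 in each hindgut, and 4 of these had more than 3 counts over the Hoxd13 midguts, while 0 of the 8 had at least 10 in each Hoxd13 midgut. In the other direction, 4 genes had at most 3 counts over the hindguts and at least 10 in each control midgut, and 2 of these had at least 10 in each Hoxd13 midgut.

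A hypothesis is that Hoxd13 moves part of the regional programme of the midgut mesoderm toward that of the hindgut. Shared controls alone do not account for the covariance of the log2 fold changes over all genes. With separate controls it was at least 0.103, where unchanged simulated groups reached at most 0.0191. With shared controls, however, the correlation and the share of genes with the same sign lay below the simulated values. Those simulated libraries were drawn independently, so deviations that real hindgut and Hoxd13 midgut libraries share are left open. The 108 common genes were called with shared controls, and 1 to 5 genes were common with separate controls. Hoxd13 midgut 4 alone does not account for the common genes, since 115 were found without it. The hypothesis was found and examined on the same libraries, and a response to any strongly expressed transcription factor may also contribute, for which no group was analysed here. A different mix of cells between the groups was not tested.

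Same-numbered control midgut and hindgut libraries deviated together, at correlations across genes of 0.435 to 0.531. A single axis that parts replicates 1 and 4 from 2 and 3 does not account for this, since libraries of the other number on the same side correlated at 0.263 or less. A shared embryo or a shared day of preparation was not tested, since the labels give neither.

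Other ways of splitting the libraries were examined in fits of the compared groups with edgeR. For hindgut against midgut, 1 of the 35 splits gave as many genes, the real one with 909, and the highest other gave 181. That split set replicates 1 and 4 of both tissues against 2 and 3 and parted no pair. Because the numbers pair these libraries, the real split compares with the 8 that part all pairs, where the highest other gave 0 genes, and 8 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split had 2421 genes and any other of the 35 at most 1287. For Hoxd13 midgut against midgut, 1 of 35 splits gave as many, the real one with 325, and the highest other gave 0, with 3055 genes at an unadjusted p under 0.05 in the real split and at most 1898 in another. For Hoxd13 midgut against hindgut, 1 of 35 gave as many, the real one with 152, and the highest other gave 21, with 3022 genes at an unadjusted p under 0.05 in the real split and up to 2505 in another. For these 2 counts the real split gave more genes than any other at the adjusted threshold, the smallest share that 35 splits allow. Mixed splits hold the real difference within both sides, where few genes can be called. The splits also concern fits of the compared groups, not the 832 and 523 genes of the main fit. Whether chance can be excluded for these 2 counts is therefore left open. For the common genes, 1 of 100 drawn regroupings gave as many, the real one with 108, and the highest other gave 0. These regroupings mixed all 12 libraries and did not keep the pairs of control midgut and hindgut, so whether chance can be excluded for the common genes is left open. At an unadjusted p under 0.05 the real groups had 542 common genes and another regrouping had 596, so the unadjusted count does not set the real groups apart.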
